A study of Mus musculus with 6 samples.

How the data were processed

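Gene expression was measured in whole brains of neonatal C57BL/6 mice on 6 Affymetrix arrays. Per the labels, each array received pooled RNA from 6 mice. The mice were injected intraperitoneally on postnatal day 2 with 1 mg of testosterone propionate (TP, an ester of testosterone) in 20 µL of sesame oil, or with the oil alone (vehicle), and brains were taken on postnatal day 6. The labels give 2 arrays of TP-treated females, 2 of vehicle-treated females, 1 of TP-treated males and 1 of vehicle-treated males. They call the later female array of each treatment a replica and do not say whether it came from a separate pool of mice. RNA was extracted with Trizol and biotin-labelled with an in vitro transcription kit, per the labels' protocols.

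The values used are the deposited log2 expression values of 45101 probe sets on each array. Per the submitters' processing notes the authors made them with RMA, which corrects background, normalizes between arrays and summarizes probes into probe sets. The version is not given in the sources used here. Array medians lay between 5.69 and 5.74 and upper quartiles between 7.84 and 7.91 on the log2 scale. The values carry no counts, so the number of arrays limits the precision. Arrays were compared for duplicates, and at most 215 probe sets had equal values in any pair. The original and replica arrays had equal values at 190 probe sets for female TP and 140 for female vehicle.

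Probe sets were named through a table of the array platform's annotation, with gene identifiers looked up in the RefSeq annotation of mouse assembly GRCm38.p6, which was used for names only. Of the probe sets, 34945 were paired with 1 gene symbol, 932 with several and 9160 had no gene in that table, and 64 were array controls. Of the single-gene probe sets, 34741 had their gene identifier in the RefSeq table, and 0 symbols needed updating. The single-gene probe sets covered 18193 genes, of which 9010 had more than 1 probe set. Each gene was represented by its probe set with the highest mean over all arrays. No gene was named from a probe set with several genes. Of 72 values of named genes in a comparison, 45 belonged to genes with more than 1 probe set, and in 24 of them another probe set had a difference of the opposite sign.

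Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, no intensity trend, two-sided), with Benjamini-Hochberg adjustment over 18193 genes and an adjusted p under 0.05 as the threshold. All adjusted p-values of single genes come from these limma fits. Female TP was compared with female vehicle on the 4 female arrays. Sex and treatment were compared in an additive model of both over all 6 arrays. The difference between the TP effect in females and that in males was a contrast in a model with 4 groups, in which the single male arrays were assumed to vary like the female ones. Male TP against male vehicle, with 1 array each, was not tested. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

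Fixed gene lists numbered 53, each with at least 5 measured genes, and covered hormone response, signalling, cell types, brain regions and neighbouring tissues. Of 992 list entries, 891 matched a measured gene, and the other entries are not analysed here. Lists were tested with camera in limma with a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation. For males, a list's median difference was placed as a percentile among 10000 random lists of genes matched on mean expression in 20 bins. Genes below the 40th percentile of mean expression, which lay at 6.19 log2 units, are called dim.

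The groups, tests, gene lists, the rule for named genes and most of the other settings were chosen before the data were examined. The rule took, per tested comparison and direction, up to 12 genes past the threshold with every array of 1 group beyond every array of the other. Where fewer passed, it added the largest differences among genes that were not dim and whose groups did not overlap, given as values that did not pass. It took the 10 highest and 10 lowest genes that were not dim in males, up to 6 per direction for the difference between the sexes' TP effects, up to 4 genes with the smallest p from each list spoken of, and a short set of sex-linked and sex hormone genes, of which 7 had a usable probe set. Further bone, hair and pituitary genes and 5 lists of hair, skin and bone genes were chosen after the values were seen.

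Other settings tried were testing all probe sets, averaging the probe sets of a gene, leaving out dim genes, quantile normalization again, centring each array on its median, an intensity trend in eBayes, the original or replica array as a block, all 6 arrays for the female comparison, 1 treatment at a time for the sex comparison, a rule of 1.5-fold change in groups that do not overlap, an estimated correlation for the lists and leaving out each female array in turn. Leaving out the male TP array and several list settings were added after the data were seen. Shared vehicle arrays were allowed for by simulating 100 data sets of unchanged groups, with noise drawn independently for each gene and array.

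Each fit was tested on simulated data with the real gene means, variances drawn from the fitted prior and 200 changed genes among 18193. In each simulation 67 genes changed by 0.5 log2 units, 67 by 1 and 66 by 2. For the female comparison 31.3%, 95.5% and 100% of these were recovered, in this order, with 3 unchanged genes among 154 called. For male against female the shares were 73.1%, 100% and 100%, with 7 unchanged genes among 189 called. For TP against vehicle in both sexes they were 76.1%, 98.5% and 98.5%, with 6 unchanged genes among 188 called. For the difference between the sexes' TP effects they were 1.49%, 44.8% and 97.0%, with 11 unchanged genes among 106 called. A simulated list of 18 genes shifted by 0.3 log2 units had a camera adjusted p of 2.22e-17 in the female comparison with the preset correlation and 0.558 with the estimated one. In the sex comparison these were 2.0e-23 and 0.0804. The estimated correlation thus missed a list that had been shifted, so failing with it does not show that a list was unchanged. The simulated genes were independent of each other. Whether the preset correlation gives false calls for lists of genes that vary together was therefore not tested.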

Results

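Whole-brain expression profiles were compared between neonatal mice given testosterone propionate (TP) and mice given sesame oil vehicle during the period when the mouse brain differentiates by sex. There were 2 female TP, 2 female vehicle, 1 male TP and 1 male vehicle arrays, each hybridised with RNA pooled from 6 mice. The SD over genes of the difference within the female TP pair was 0.14 log2 units, within the female vehicle pair 0.17 and between the male TP and vehicle arrays 0.18. Because the labels do not say that the replica female arrays came from separate pools, the p-values measure the spread between arrays, which may be technical. The small number of arrays limited the precision of every comparison.

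The first comparison asked which genes TP changed in the female brain. Ibsp, encoding the bone matrix protein integrin-binding sialoprotein, rose 3.11-fold with TP, from 4.48 ± 0.09 log2 units in vehicle arrays to 6.11 ± 0.11 in TP arrays (SD, n = 2 each; limma adjusted p = 0.0125). This is the brighter of its 2 probe sets, and the other had a log2 difference of 0.38. Of the genes for keratin-associated proteins, which are structural proteins of the hair shaft, 4 fell. Krtap16-3 fell by 1.52 log2 units (SE 0.11, adjusted p = 0.0269) and Krtap15 fell by 1.23 log2 units (SE 0.09, adjusted p = 0.0269). Krtap19-5 fell by 1.21 log2 units (SE 0.07, adjusted p = 0.0125) and Krtap22-2 fell by 1.07 log2 units (SE 0.08, adjusted p = 0.0269). No detection call was used here, and with TP means of 2.46 for Krtap16-3 and 2.66 for Krtap19-5, on arrays with minima of 2.11 and 2.16, the sizes of these differences are uncertain. All 5 are dim genes, and for each both TP arrays lay beyond both vehicle arrays.

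These were the genes that passed in females, 1 higher and 4 lower of 18193, while 1356 genes had an unadjusted p under 0.05 against 910 by chance. The female groups did not overlap for 38.1% of genes, where chance gives 33.3%. The male arrays gave other levels for the same genes. Ibsp stood at 4.61 in the male vehicle and 3.49 in the male TP array, Krtap16-3 at 2.65 and 2.49, Krtap15 at 3.14 and 3.19, Krtap19-5 at 3.28 and 2.61 and Krtap22-2 at 3.50 and 3.19. For these 4 Krtap genes the TP effects of the sexes did not differ past the threshold (smallest adjusted p = 0.569). Leaving out any 1 of the 4 female arrays, which leaves a group with 1 array assumed to vary like the other group, left 0 genes past the limma threshold, with 728 to 2257 at an unadjusted p under 0.05, and the adjusted p of Ibsp was 0.634 without TP array 1, 0.446 without TP array 2, 0.184 without vehicle array 1 and 0.163 without vehicle array 2, while that of the Krtap genes ranged from 0.139 to 0.926. The differences moved little, from 1.56 to 1.71 for Ibsp and from -1.22 to -1.20 for Krtap19-5. With dim genes left out 0 passed (981 at an unadjusted p under 0.05), and with the mean of a gene's probe sets Ibsp had a difference of 1.01 (adjusted p = 0.0555) and Krtap16-3 of -1.23 (adjusted p = 0.319). With all probe sets tested one by one 5 passed again, but 4 were higher and 1 lower: Ibsp and Krtap19-5 were kept, 3 were new, and Krtap15, Krtap16-3 and Krtap22-2 had adjusted p of 0.0613, 0.0561 and 0.0613.

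**Figure D1:**
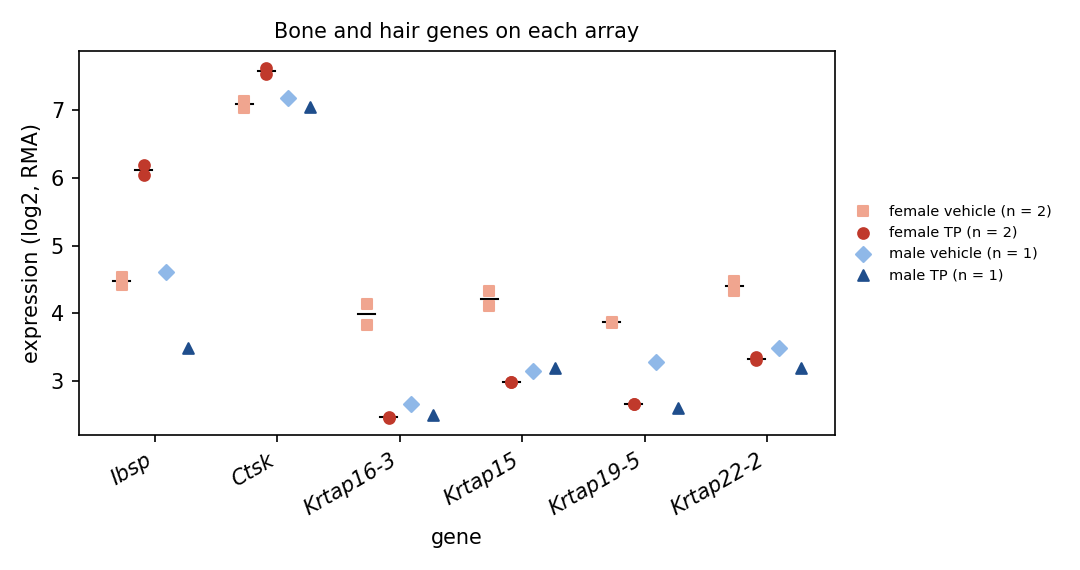
Expression (log2, RMA) of bone and hair genes on each array. Points are arrays, coloured by group, and black lines are means of groups with 2 arrays. Ibsp lies at 6.11 on average in female TP arrays and 4.48 in female vehicle arrays, and the 4 Krtap genes lie lower in the female TP arrays, the female vehicle arrays standing above all others.

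Other genes of bone gave higher values without passing, and these and the further hair genes were chosen after the values were seen, except Ctsk and Dmp1. The log2 difference was 1.12 (SE 0.17) for Dmp1, a mineralization protein of osteocytes, and 0.99 (SE 0.13) for Acp5, the acid phosphatase of osteoclasts. It was 0.82 for Mmp13, a collagenase, 0.79 for Phex, a phosphate-regulating endopeptidase, and 0.49 for Ctsk, a protease of osteoclasts. In a list of 14 osteoclast genes drawn up after the values were seen, 9 had positive and 5 negative differences. Of the 13 genes of the fixed cartilage and bone list, 1 (Ibsp) was higher over all genes and 2 (Ibsp and Dmp1) were higher adjusted over the list alone, while 9 members had negative differences, and the list itself did not pass (median -0.06, mean 0.13, adjusted p = 0.828). Hair genes were lower without passing for Krtap8-1 (-1.95, adjusted p = 0.0935), Krtap19-9b (-0.87, adjusted p = 0.0935) and Prr9 (-0.92). Of genes that were not dim and whose groups did not overlap, the largest values without passing after Ctsk were 0.48 for Taf15, 0.43 for Pkdcc and 0.41 for both Erdr1 and Slc7a11, a cystine transporter. Washc4 and Fam131b stood at 0.40, Ell2, an elongation factor, at 0.39, and Serf1, Asxl2 and 4632427E13Rik at 0.38. The groups barely separated for Serf1, at 10.31 in female vehicle array 2 and 10.32 in female TP array 2. Lower values were -0.54 for Sars2, a mitochondrial seryl-tRNA synthetase, -0.51 for Gm15706, -0.40 for Prmt1, an arginine methyltransferase, and -0.39 for Cpxm1, Eml2 and Hoxb5. Anxa1 and Ccl28 both stood at -0.38. Of these, Pkdcc, Fam131b, Ell2, Serf1, Asxl2, 4632427E13Rik, Anxa1 and Ccl28 had another probe set with a difference of the opposite sign.

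Among the fixed lists, markers of hindbrain and spinal cord fell in TP females. Of 21 measured members, 18 had negative differences (median -0.11, list adjusted p = 0.0202), 0 passed over all genes and 0 passed adjusted over the list alone. With an estimated correlation the list's adjusted p was 0.961. Its members with the smallest p were the homeobox genes Hoxb5 (-0.39), Hoxc5 (-0.28) and Hoxb4 (-0.32) and Slc6a5, the glycine transporter of inhibitory neurons (-0.38). Leaving out the female TP array 1, vehicle array 1 or vehicle array 2 gave adjusted p of 0.413, 0.316 and 0.0856 for this list. Blood genes gave small values beside this. In the erythroid list of 12 genes (median -0.01, mean 0.04) 3 genes, Slc4a1 (0.29), Alas2 (0.32) and Hbb-b2 (0.29), were higher when adjusted over the list alone, with the list itself at adjusted p = 0.413, and in the leukocyte list Camp (-0.36), an antimicrobial peptide of neutrophils, was lower on the same basis, the list standing at adjusted p = 0.905.

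Lists tied to sex steroids did not pass in females. The adjusted p was 0.708 for 22 genes of sex steroid receptors and metabolism, 0.413 for 38 androgen response genes, 0.828 for 26 estrogen response genes and 0.934 for 20 genes of brain sexual dimorphism. It was 0.973 for 23 glucocorticoid response genes and 0.828 for 19 hypothalamic reproductive peptides and receptors. In each of these lists 0 genes passed over all genes or adjusted over the list alone. The estrogen receptor genes Esr1 and Esr2 had differences of -0.12 (adjusted p = 0.798) and -0.34 (adjusted p = 0.606), and Pgr, the progesterone receptor, 0.09 (adjusted p = 0.885). Xist, the RNA that silences an X chromosome in females, had 0.16 (adjusted p = 0.696). Lists of the cerebral cortex (0.222), glutamate receptors and transporters (0.197), monoamine system (0.197) and neural stem cells and radial glia (0.197) had the next smallest adjusted p.

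Male and female brains were compared over both treatments, adjusting for treatment. The Y-linked genes Eif2s3y, a translation initiation factor, Kdm5d, a histone demethylase, and Uty, a homologue of a histone demethylase, were higher in males by 6.18 (SE 0.06, adjusted p = 2.88e-08), 4.42 (SE 0.11, adjusted p = 7.17e-06) and 2.57 (SE 0.15, adjusted p = 0.0020) log2 units, with both male arrays above all 4 female arrays. Females carry no Y chromosome, so their values are background and the sizes of these differences are lower bounds. Of the X-linked partners, Eif2s3x had -0.55 (SE 0.06, adjusted p = 0.0714). Xist differed by -4.87 (SE 0.93, adjusted p = 0.234), with 12.66 ± 0.07 in female vehicle and 12.82 ± 0.02 in female TP arrays (SD, n = 2 each), 5.29 in the male vehicle array and 10.45 in the male TP array. Without the male TP array the difference was -7.37 (adjusted p = 1.65e-06).

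**Figure D2:**
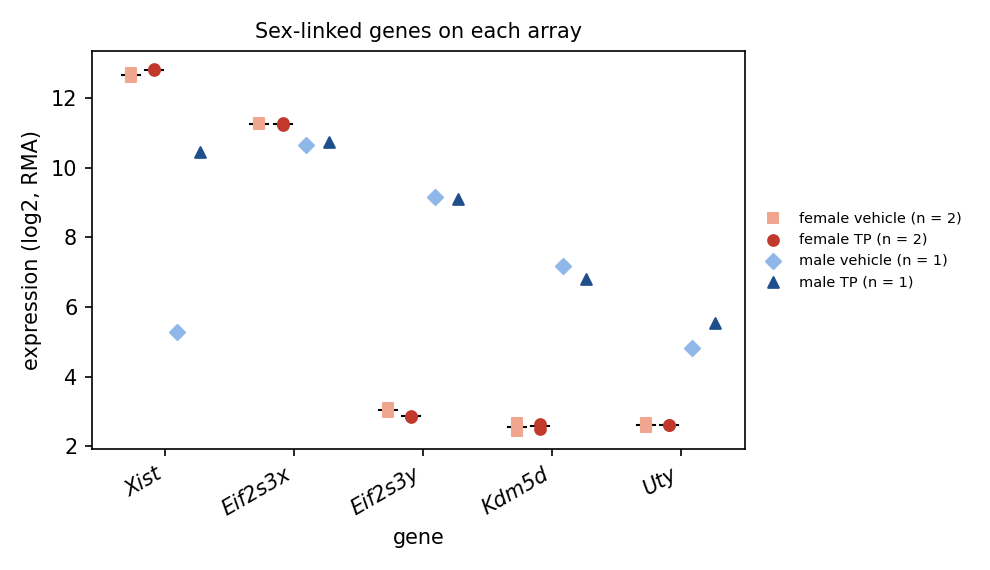
Expression (log2, RMA) of 5 sex-linked genes on each array, with points as arrays and black lines as means of groups with 2 arrays. Eif2s3y, Kdm5d and Uty lie higher in both male arrays than in all 4 female arrays, and Xist in the male TP array, at 10.45, lies between the male vehicle array at 5.29 and the females.

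In all, 3 genes were higher and 0 lower in males by limma, while 2550 had an unadjusted p under 0.05, and groups did not overlap for 22.2% of genes, where chance gives 13.3%. Beside Xist and Eif2s3x, values without passing, among genes that were not dim and whose groups did not overlap, were led by Gm6958 (-0.73, adjusted p = 0.0532), 5530601H04Rik (-0.57), Pcp2 of Purkinje cells (-0.52), the transcription factor Insm1 (-0.52) and Hoxa5 (-0.51). Spc25, of the kinetochore, had -0.49 (adjusted p = 0.0947), Cdca5 and Cenpe -0.45, Skor1 -0.44 and Serpinb1b -0.43. Higher values were 0.37 for Gm5802 and Slc17a9, 0.33 for Ust, 1810044D09Rik and Tff1, 0.32 for Gm14198 and Gpr83, 0.31 for Pik3cd and 0.30 for Taf1. With the intensity trend 24 genes passed, 5 higher and 19 lower, and among genes that were not dim 10 passed, all lower, with Gm6958, Eif2s3x and Spc25 at adjusted p of 0.0045, 0.0055 and 0.0073. Slc17a9, Ust, 1810044D09Rik, Gpr83, Pik3cd, Spc25 and Skor1 had another probe set with a difference of the opposite sign. Esr1, Esr2 and Pgr differed by -0.11, 0.12 and -0.25.

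Lists differed between the sexes in 11 cases, 4 higher and 7 lower in males, at the preset correlation. With an estimated correlation 0 of the 11 passed, the smallest adjusted p being 0.203 for the Y-linked and cycling progenitor lists. As even the Y-linked list did not pass, this setting cannot decide about the others. Among 21 markers of cycling progenitors, 20 were lower in males (median -0.23, adjusted p = 2.42e-10), 15 of them adjusted over the list alone and 0 over all genes, with the mitotic genes Ccnb2 (-0.40), Cdk1 (-0.34) and Birc5 (-0.28) and the replication helicase Mcm5 (-0.30). Among 19 cerebellum markers 17 were lower (median -0.22, adjusted p = 1.30e-05, adjusted p = 0.222 with an estimated correlation), 9 adjusted over the list alone, with Pcp2, Zic2 (-0.29), Neurod1 (-0.36) and En2 (-0.28). X inactivation and escape genes were lower (10 genes, 4 adjusted over the list alone, adjusted p = 9.67e-04, adjusted p = 0.515 with an estimated correlation), among them Kdm5c (-0.30) and Pbdc1 (-0.24). The Y-linked list was higher (6 genes, 5 over the list alone, adjusted p = 5.94e-14, adjusted p = 0.203 with an estimated correlation).

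Blood leukocyte markers were higher in males as a list (12 genes, median 0.15, adjusted p = 9.67e-04, adjusted p = 0.515 with an estimated correlation), 4 adjusted over the list alone, namely S100a8 (0.60), S100a9 (0.56), Mpo (0.46) and Camp (0.31), genes of neutrophils and their precursors. All 16 cholesterol biosynthesis genes were lower (median -0.09, adjusted p = 0.0173, adjusted p = 0.539 with an estimated correlation), with Idi1 at -0.19 and Fdps at -0.17 and 0 passing adjusted over the list alone. Neural stem and radial glia markers (12 genes, 11 lower, adjusted p = 0.0192, adjusted p = 0.515 with an estimated correlation, Pax6 at -0.35), targets of the Wnt and hedgehog pathways (14 genes, 12 lower, adjusted p = 0.0279, adjusted p = 0.515 with an estimated correlation, Gli2 at -0.33) and oxidative phosphorylation genes (21 genes, 19 lower, adjusted p = 0.0364, adjusted p = 0.515 with an estimated correlation, Ndufa4 at -0.16) were lower too. Each of the former pair had 1 gene adjusted over the list alone and the latter 0. Pituitary markers (13 genes, 10 higher, median 0.15, adjusted p = 0.0279, adjusted p = 0.539 with an estimated correlation) and pineal and retina markers (14 genes, 10 higher, adjusted p = 0.0411, adjusted p = 0.515 with an estimated correlation, Aanat at 0.32 and Cryaa at 0.24) were higher. Without the male TP array the pituitary list's mean was -0.0049 (adjusted p = 0.950) and 7 lists passed, 3 higher and 4 lower, and neural stem, Wnt and hedgehog, oxidative phosphorylation and pineal and retina lists no longer did (adjusted p of 0.302, 0.216, 0.219 and 0.176). Leaving out dim genes ended calls for cholesterol biosynthesis, neural stem, oxidative phosphorylation and Wnt and hedgehog lists (adjusted p of 0.101, 0.146, 0.316 and 0.421), and with vehicle arrays alone cholesterol biosynthesis stood at 0.0528. Leaving out 1 female array ended calls for cholesterol biosynthesis (0.0595 without vehicle array 2), neural stem markers (0.0746 without vehicle array 2), oxidative phosphorylation (0.0888 without vehicle array 1 and 0.0766 without TP array 2), pituitary (0.0501 without TP array 1 and 0.0629 without TP array 2) and pineal and retina, whose adjusted p was 0.0501 and 0.0766 without TP arrays 1 and 2 and 0.0685 and 0.0645 without vehicle arrays 1 and 2.

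TP was next compared with vehicle over both sexes, adjusting for sex. The list of hindbrain and spinal cord markers fell and that of glutamate receptors and transporters rose at the preset correlation. With an estimated correlation both lists stood at adjusted p = 0.852. Of the hindbrain list's 21 genes 17 were negative (median -0.21, adjusted p = 0.0062), 6 adjusted over the list alone, among them Slc6a5 (-0.41, SE 0.07), Hoxb5 (-0.51, SE 0.09), Hoxb3 (-0.35) and Hoxd3 (-0.37). Of 20 glutamate genes 15 were positive (median 0.02, adjusted p = 0.0231), 0 adjusted over the list alone, with the ionotropic receptor genes Gria3 and Grik3 at 0.26 each, Grin2b at 0.16 and Grm5 at 0.18. By limma 0 single genes passed (smallest adjusted p = 0.290), while 2229 had an unadjusted p under 0.05 and the groups of 3 arrays did not overlap for 14.9% of genes, where chance gives 10%. Without the male TP array, which leaves the female difference alone, 5 genes passed, and with the intensity trend 7 did, among them Erdr1 (adjusted p = 0.0031), Gm15706 (0.0169) and Eml2 (0.0148).

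Among genes that were not dim and whose groups did not overlap, values in this comparison were highest for Serf1 (0.50, SE 0.17), Asxl2 and Washc4 (0.45), Eif2a and Erdr1 (0.42) and 5031426D15Rik (0.40). Srsf12 and Tra2a, which bind RNA in splicing, stood at 0.39 and 0.38, Zfp141 and Gm9222 at 0.39 and Pkdcc and Slc7a11 at 0.38. For some of these genes the groups barely separated. Female vehicle array 2 stood at 10.31 for Serf1, 8.881 for Srsf12 and 8.32 for Eif2a. Female TP array 2 stood at 10.32, 8.884 and 8.36. Lowest after Hoxb5 among the same genes were Gm15706 (-0.49), Sars2 (-0.48), Mpst and Eml2 (-0.43), Slc6a5 (-0.41), Epha8 (-0.40), 9330133O14Rik (-0.38), Fance (-0.35), Cpxm1 and H6pd (-0.33) and Pex5l (-0.32). Another probe set had a difference of the opposite sign for Pkdcc, Slc7a11, Serf1, Asxl2, Eif2a, Tra2a, Slc6a5, Fance and Pex5l. In the brain sexual dimorphism list, Dgkk, a diacylglycerol kinase (0.28), and Gal, the neuropeptide galanin (-0.23), passed when adjusted over the list alone (0.0345 and 0.0484) and not over all genes (0.297 and 0.324).

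In males, TP and vehicle were compared on 1 array each, without a test. The male TP array had 27 genes at least 1.5-fold higher and 52 lower than the male vehicle array, against 84 genes at least 1.5-fold apart within the female vehicle pair and 18 within the female TP pair. After quantile normalization the split was 49 higher and 29 lower, and after centring on array medians 48 and 21. Among genes that were not dim, the highest values beside Xist (5.16) were for Pomc, the precursor of pituitary ACTH (1.40), Serf1, Eif2a and 2610008E11Rik (0.73), Anks1b, Srsf12 and Zdhhc20 (0.64), 5031426D15Rik (0.60) and Pcdh7 (0.59). The lowest among these were Hoxa5 (-0.84), Mobp, a myelin protein gene (-0.79), Hoxb5 (-0.76), Unc5b (-0.66), 2700049A03Rik and Mpst (-0.61), Tlx2 (-0.59), Hoxb3 (-0.56) and Mag and Tmem204 (-0.55). Of 53 list medians, 8 lay within 2.5 percentile points of either end of 10000 matched random lists. The random lists were drawn gene by gene, which ignores correlation between the genes of a list. With 1 array per treatment these percentiles are therefore not a test of TP. Low ones were those of myelinating oligodendrocytes (-0.23, percentile 0), olfactory bulb (-0.21, percentile 0.01), hindbrain and spinal cord (-0.20, percentile 0.03), meninges and fibroblasts (-0.13, percentile 0.32), pan-neuronal genes (-0.07, percentile 1.04) and blood leukocytes (-0.20, percentile 1.59). High ones were those of brain sexual dimorphism genes (0.05, percentile 97.8) and pituitary (0.17, percentile 99.97). Averaging all probe sets of a gene, an alternative chosen after the data were seen, gave 1.69 for Pomc, 0.24 for Serf1, 0.29 for Eif2a, 0.06 for Anks1b, 0.40 for Zdhhc20, 0.25 for Pcdh7, -0.52 for Hoxa5, -0.43 for Mobp, -0.30 for Unc5b, -0.31 for 2700049A03Rik and -0.26 for Tmem204.

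**Figure D3:**
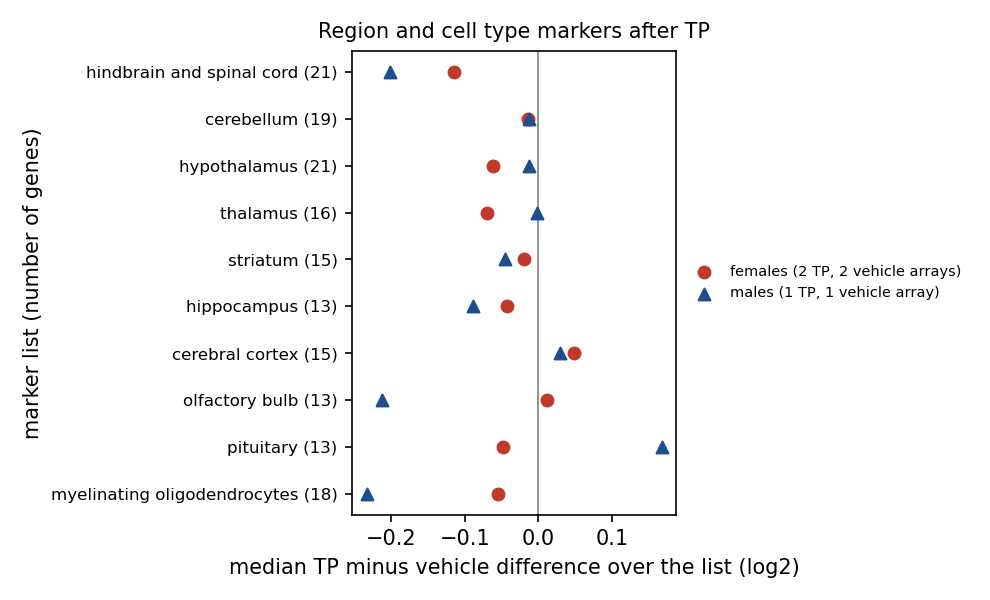
Median TP minus vehicle difference (log2) of marker lists, with the number of genes in parentheses, in females as circles (2 TP and 2 vehicle arrays) and males as triangles (1 TP and 1 vehicle array). Hindbrain and spinal cord markers lie at -0.11 in females and -0.20 in males, and pituitary markers at 0.17 in males.

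The TP effect differed between females and males for 2 genes by limma, with 804 genes at an unadjusted p under 0.05, fewer than the 910 by chance. Ibsp was 2.75 log2 units (SE 0.15, adjusted p = 0.0102) higher in the female than in the male TP effect, being 1.64 in females and -1.11 in males. Xist was lower by the same measure (-4.995, SE 0.13, adjusted p = 1.71e-04), with 0.16 in females and 5.16 in males. Growth hormone, Gh, had -2.89 (adjusted p = 0.0752) on its brightest probe set. On 3 of its 4 probe sets, tested one by one, it had -5.30, -5.17 and -4.90 (adjusted p of 2.17e-04, 2.31e-04 and 2.73e-04). These 3 stood at 3.37 or lower on the 5 arrays other than male TP, near the lower end of the signal range, so the sizes are uncertain. These Gh probe sets were chosen after the values were seen. Leaving out any 1 female array left 1 gene past the threshold, with Ibsp at adjusted p of 0.293 and 0.229 without TP arrays 1 and 2 and 0.127 and 0.104 without vehicle arrays 1 and 2. With the mean of its probe sets Ibsp had 1.65 (adjusted p = 0.102).

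Lists of pituitary (13 genes, adjusted p = 3.56e-04, 2 genes lower adjusted over the list alone, Gh and Pomc at -1.41), myelinating oligodendrocyte (18 genes, adjusted p = 0.0012, Mobp at 0.80), olfactory bulb (13 genes, adjusted p = 0.0026, Cdhr1 at 0.58) and X inactivation and escape genes (10 genes, adjusted p = 0.0082, 1 adjusted over the list alone) differed in TP effect between the sexes at the preset correlation. With an estimated correlation all 4 stood at adjusted p = 0.958. In the X list the 1 gene was Xist. The female effect was the lower one for the pituitary and X lists and the higher one for the others, and each of the myelin and bulb lists had 1 gene adjusted over the list alone. Without female vehicle array 2 the X list stood at 0.0933.

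Whether TP moved female brains toward male levels was asked across 18177 genes outside the sex-linked lists, which are not independent replicates. The covariance of the female TP difference with the male minus female difference of vehicle arrays was 0.0038, against 0.0043 in simulated unchanged groups sharing the female vehicle arrays, and the correlation was 0.198 against 0.410. With female vehicle array 1 in the TP difference and array 2 in the sex difference the covariance was -0.0077. With the arrays exchanged it was 0.0011, and the simulated values were 3.23e-05 and 2.45e-05. The simulated noise was independent between genes, so it held no deviation shared by many genes of an array. As the sign also changed with the vehicle array used, the question could not be decided. Female and male TP differences, which share no array, correlated across genes with r = 0.271 (Spearman rho 0.291). Over 10907 genes that were not dim r was 0.444 (rho 0.414). The male vehicle array lay closer to female vehicle array 1 (SD of log2 differences 0.201) than to array 2 (0.224). The male TP array likewise lay closer to female TP array 1 (0.189) than to array 2 (0.203). Deviations shared by these arrays would also raise r, which was not tested.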

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

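The comparison of TP effects between the sexes was part of the design. The tests that weigh explanations, those of single Gh probe sets and the count of splits were chosen only after the results were seen. Several differences between the sexes' TP effects, each the female effect minus the male one in log2 units, stood out by a test of the difference itself. They were 2.75 for Ibsp, -4.995 for Xist and -5.30, -5.17 and -4.90 for 3 of the 4 probe sets of Gh. For lists, the mean differences were 0.18 for myelinating oligodendrocytes (median 0.17), 0.20 for the olfactory bulb (median 0.22), -0.53 for pituitary (median -0.05, 5 genes positive and 8 negative) and -0.57 for X inactivation and escape genes (median -0.10, 3 positive and 7 negative). The mean of the X list lay mostly in Xist and that of the pituitary list in Gh (-2.89), Pomc (-1.41) and Tshb (-1.15). With an estimated correlation these lists had an adjusted p of 0.958. Probe sets without a single gene in the annotation used, which the report's comparisons leave out, passed in 2 cases for TP in females, 6 for male against female and 4 for TP in both sexes.

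In the male TP array Xist stood at 10.45, between 5.29 in the male vehicle array and 12.82 ± 0.02 (SD, n = 2) in TP females. The tables argue against an array from another sex under this label, since the smallest Y-linked signal of that array lay 2.86 log2 units above the highest female array. The log2 TP difference of Xist was 0.16 in females and 5.16 in males, which goes against a like fold rise (limma interaction adjusted p = 1.71e-04). That p rests on 1 male array per treatment, and a like rise on the linear scale was not tested, so a like effect stays open. Female tissue in the male TP pool may account for the Xist level and stays open. On the linear scale Xist reached 19.9% of the female level. From log2 differences, an unlike measure, 5 genes that escape X inactivation gave a female share of 20.0% with a standard error of 16.0%. As 1 mouse of the pool would give 16.7%, the error of that share keeps the explanation from being decided. Female tissue would also lower Y-linked genes. From the male vehicle to the male TP array Eif2s3y changed by -0.04, Kdm5d by -0.37 and Uty by 0.71 (mean 0.10, SD 0.55), too wide a spread to decide. A TP effect on Xist in males alone also stays open as untested, with 1 array.

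With TP in females, 4 keratin-associated genes were lower and Ibsp was higher, while the fixed cartilage and bone list did not pass (9 of 13 genes negative, adjusted p = 0.828). All dim genes had a median of -0.05 and 38 keratin-associated genes one of -0.30, so a shift of all dim genes alike does not reach that size. The keratin-associated median lay at percentile 0 of matched random lists, whose lowest median was -0.145. That list was drawn up after the values were seen, and correlation between these similar probe sets is ignored there, so the percentile cannot decide. The difference for Ibsp, 1.64 in females and -1.11 in males, goes against a like rise (interaction adjusted p = 0.0102, and 2.68 to 2.83 log2 units without any 1 female array), but it was 1.65 with the mean of probe sets (adjusted p = 0.102) and its male side is 1 array per treatment, so a like effect stays open. For the keratin-associated list the interaction had a camera adjusted p of 1.76e-17 with the preset and 0.756 with an estimated correlation. The latter setting also missed a simulated shifted list, and males had 1 array per treatment, so a like fall of that list stays open too. Scalp skin in the female vehicle pools and skull bone in the female TP pools may account for the pattern and stay open. In lists drawn up after the values were seen, 18 epidermal genes, 4 of them not dim, had a median of -0.0691 (SD 0.12). Of these 18 genes 16 were negative and 2 positive, with 7 lower and 1 higher in both TP arrays than in both vehicle arrays. Of 27 genes of bone cells and osteoclasts, 10 were higher and 5 lower in both TP arrays than in both vehicle arrays. The bone cell genes gave 7 higher and 1 lower, but the osteoclast genes 3 higher and 4 lower. Over all genes the female groups did not overlap for 38.1%. A TP effect in females stays open too.

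In the male TP array the median of pituitary genes was higher, and those of hindbrain, myelin and olfactory bulb genes were lower, than in the male vehicle array. Of 13 pituitary genes 8 were higher and 5 lower. The hormone genes differed by 2.84 for Gh on its brightest probe set, 1.40 for Pomc, 0.93 for Tshb, 0.40 for Prl, 0.35 for Cga, -0.03 for Lhb and -0.09 for Fshb. The interaction for Gh goes against TP raising pituitary hormone genes alike in both sexes (limma smallest adjusted p = 2.17e-04). For the same 3 probe sets it was -5.37 to -4.82 log2 units without any 1 female array. The Gh probe set with the largest difference stood at 8.66 in the male TP array and 3.18 in the male vehicle array. These probe sets were chosen after the values were seen and lay near the lower end of the signal range on the other arrays. In females the same 3 probe sets differed by 0.18, -0.03 and 0.12, so a rise of the male size was not seen there. With 1 male array per treatment, a smaller like effect stays open. A dissection that reached farther at the base and less far at the ends of the brain may account for the pattern: the medians of 6 of 6 lists of inner regions lay more than 2.5 percentile points from either end of random lists and those of the 4 lists of the pattern closer, but these values had been seen before, and the lists of pan-neuronal genes (percentile 1.04), meninges (percentile 0.32), blood leukocytes (percentile 1.59) and brain sexual dimorphism genes (percentile 97.8) lay within the same distance of an end. Whether TP lowered hindbrain genes alike in both sexes cannot be told apart from this, the list's interaction having an adjusted p of 0.129 and males 1 array per treatment. A TP effect in males stays open for the same lack of arrays.

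For TP against vehicle in both sexes, the 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. By limma the real split gave 0 genes and the highest of the others 0, with 2229 and at most 1629 genes at an unadjusted p under 0.05.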

How the results depend on the processing

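Settings that left out the male TP array, added lists of hair, skin and bone genes, used vehicle arrays alone for the lists between the sexes, or changed the lists of the both-sexes and interaction comparisons were chosen after seeing the data. Where no cause is named, the cause was not tested. Over 198 single genes and lists and 2117 values under other settings, 1974 kept their direction and, where tested, their side of the threshold, 77 no longer passed, 40 newly passed, 11 untested values moved and 15 changed sign. Untested male values counted as kept where they moved by no more than the gene's spread. Most of the 198 had not passed in the main fits, so the kept values say little about whether the calls hold.

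For TP in females, where 5 genes passed, all probe sets gave 5 (4 higher and 1 lower, 2 kept and 3 new), the mean of a gene's probe sets gave 3, leaving out dim genes 0 (none of the 5 was then tested; 981 at an unadjusted p under 0.05), the intensity trend 15 and a rule of 1.5-fold change without overlap 19. Leaving out 1 array gave 0 to 0 genes by limma (728 to 2257 at an unadjusted p under 0.05). For male against female, with 3 genes, testing all probe sets gave 10, leaving out dim genes 10 (none of the 3 was then tested), the intensity trend 24 and TP arrays alone 6. For TP in both sexes, with 0 genes, all probe sets gave 4, leaving out dim genes 1, the intensity trend 7 and leaving out the male TP array 5, which by construction are those of the female comparison. For the difference between the sexes' TP effects, with 2 genes, all probe sets gave 7, the trend 6 and leaving out 1 array 1 to 1. In males, with 79 genes, all probe sets gave 475 and leaving out dim genes 17.

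Of the lists, an estimated correlation left 0 of 1, 0 of 11, 0 of 2 and 0 of 4 in the same order of comparisons. A simulated list shifted by 0.3 log2 units did not pass with it either (camera adjusted p of 0.558 in the female and 0.0804 in the sex comparison). It therefore cannot decide whether a list changed. Passing with the preset correlation does not settle it either, as that setting was not tested on genes that vary together. The added lists took the female count to 4, and leaving out 1 array gave 0 to 1. Between the sexes leaving out dim genes gave 6 lists, leaving out the male TP array 7 and vehicle arrays alone 5, and for TP in both sexes leaving out 1 array gave 2 to 4. The covariance of sex difference and TP response minus its simulated value, -4.75e-04, became -0.0078 and 0.0010 with the female vehicle arrays split and -0.0021 without dim genes.

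Signs changed in these cases. In females Uty had 0.015 after quantile normalization, 0.024 after centring and -0.075 to 0.041 on leaving out 1 array, Kdm5d -0.084 to 0.14 and Pgr -0.058 to 0.23. Between the sexes Pgr, at -0.25, had 0.017 with the mean of probe sets, and the pituitary list, which had passed with a mean of 0.26, -0.0049 without the male TP array and with vehicle arrays alone. For TP in both sexes Kdm5d had 0.028 and Uty, at 0.22, -0.017 without the male TP array, and Pgr -0.019 to 0.15 on leaving out 1 array. In the difference between the sexes' TP effects Esr1 had 0.0097 with the mean of probe sets and -0.19 to 0.030 on leaving out 1 array, and Pgr -0.090 to 0.20.

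The female arrays share only the words original and replica. Deviations of the original arrays from their group means correlated across genes with r = 0.110 between the groups. With this number as a replicate block 5 genes passed in females, 4 of them as before, Krtap8-1 newly passing (adjusted p = 0.0091) and Krtap22-2 not (0.0509). It gave 2 genes between the sexes, Uty not passing (0.0579), and 0 for TP in both sexes, and 1 list passed in females. Genes near the lower end of the signal range, where the 4 Krtap calls lie, are measured with the least signal over background.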

Other observations

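Of 14 measured targets of the Wnt and hedgehog pathways, which pattern the embryonic and early postnatal brain, 4 were lower with TP over both sexes when adjusted over the list alone, each at 0.0176. The list did not pass as a whole (median -0.08, 11 negative, adjusted p = 0.230, adjusted p = 0.852 with an estimated correlation). The 4 were Hhip, a hedgehog-binding inhibitor (-0.37, SE 0.08), Gli1, a hedgehog-induced transcription factor (-0.34, SE 0.08), Lgr5, a receptor that enhances Wnt signalling (-0.26), and Sp5, a transcription factor induced by Wnt (-0.28). In females alone Sp5 (-0.35) and Hhip (-0.42) passed adjusted over the list alone, both at 0.0306. By limma 0 of them passed over all genes.

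Noncoding genes of the X inactivation centre had differences with TP in both sexes that passed when adjusted over their list of 10 alone, and not over all genes. Jpx, an RNA that activates Xist, had -0.29 (SE 0.06, 0.0104), Tsix, the antisense repressor of Xist, -0.25 (SE 0.06, 0.0124) and Ftx 0.26 (SE 0.07, 0.0296). Tsix lay near the lower end of the signal range, at a mean of 2.87 log2 units. In other lists of the same comparison, Mog of myelin had -0.36 (0.0218 over its list alone), Igfbpl1 of newborn neurons -0.30 (0.0178) and Robo2, an axon guidance receptor, 0.41 (0.0463). Mog had -0.30 in females and -0.46 in males, and the median of its list was -0.06 in females and -0.23 in males, with 1 male array per treatment. The list's TP effect differed between the sexes at the preset correlation (adjusted p = 0.0012, adjusted p = 0.958 with an estimated correlation).

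The 5 lists of hair, skin and bone genes drawn up after the values were seen gave these medians for TP in females. The median was -0.30 for 38 keratin-associated genes (36 negative, camera adjusted p = 5.95e-18). It was -0.17 for 28 hair follicle keratins and related genes (24 negative, camera adjusted p = 2.83e-06). For 13 genes of bone cells it was 0.13 (10 positive, camera adjusted p = 4.62e-06). For 14 genes of osteoclasts it was 0.04 (9 positive, camera adjusted p = 0.150). For 18 genes of epidermis it was -0.07 (16 negative, camera adjusted p = 0.321). With an estimated correlation each had an adjusted p of 0.844. The medians in males were 0.03, -0.04, -0.17, -0.12 and -0.12 in the same order.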
